A study of Mus musculus with 9 samples.

How the data were processed

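The study transplanted left lungs from C57BL/6 donor mice into Balb/C recipients and measured the RNA of whole left lungs. Per the labels' protocols, 1 µg of total RNA entered each library, libraries were made with the NEBNext Ultra II RNA kit, and paired reads of 150 bp came from an Illumina NovaSeq. The labels do not state whether the kit kept the strand of the RNA, so reads of genes that overlap on opposite strands may not be parted. The 9 libraries form 3 groups of 3, which are naive lungs, grafts after cold ischemia and reperfusion, and grafts from donors put through hypovolemic shock before the same cold ischemia and reperfusion. Each library entered the group that its sample title gives. The titles number the lungs within a group and do not name the animals, so p-values of single genes measure the spread between these samples.

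The authors deposited 3 tables, 1 for each pair of groups, with 6 libraries in each. The read counts per gene are whole numbers with no normalization, per the file headers. The tables' normalized signal was the count of a gene divided by 1 size factor per library, which was checked on the deposited values. The deposited FPKM values, which scale reads by gene length and library total, were read only to check their unit. The log2 fold change and the p-value with its adjusted p-value in each table are the authors' deposited results, and the normalization behind them is the authors' own. Per the submitters' processing notes, STAR, HTSeq, DESeq2, edgeR and STAR-Fusion were used with the genome build mm10, and neither their versions nor the role of each is stated there. The gene annotation behind the counts is not given in the sources used here. Of the 23944 gene identifiers, 23673 (98.9%) were found in GENCODE release M21 for mm10, and 23658 of these overlapped the place given in the tables. Coordinates are those of the deposited tables.

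The 3 tables were joined by gene identifier. Every library stands in a pair of tables, and the 9 repeats held no count that differed. Pairs of libraries were compared by a chi-square test of their counts over genes with at least 10 reads in the pair. The lowest value was 15.0 per degree of freedom, between naive replicates 1 and 2, so no library repeated another within sampling noise.

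Total counts ran from 18913487 in naive replicate 2 to 34986276 in naive replicate 3. At these depths a gene with no read in the shallowest naive library could still have had up to 0.136 CPM (counts scaled to library size), taking 3 reads as the floor and library sizes scaled by TMM. Intervals and floors cover counting error only. Where all libraries of a group had no read, the fold is given as a lower bound against the floor of that group, and where a group had 1 to 3 reads in total, the ratio is given with its exact 95% counting interval.

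Genes were tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, two-sided, after TMM scaling and the filterByExpr filter, which kept 15834 genes. All 9 libraries entered 1 fit with a mean per group, which left 6 residual degrees of freedom before moderation. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called. Levels are CPM on TMM-scaled library sizes, given as mean ± SD over the 3 libraries of a group, and ± after a log2 fold change is its standard error from the fit. Principal components were computed from log2 CPM with a prior count of 2.

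Lists of genes for cell types, pathways and RNA composition, 47 in all, were fixed before the data were examined, as were the groups, the test, the rule for named genes and the alternative settings listed further on. Lists with at least 3 tested genes, 46 of them, were tested with camera from limma 3.58.1, which asks whether the genes of a list are ranked higher or lower than the other genes, with a preset correlation between genes of 0.01. Adjusted p-values of lists were computed over the 46 lists of a comparison. With the preset correlation, a camera p-value rests mainly on the spread across genes and not on that between samples. The same test was run with the correlation estimated for each list. The rotation test fry was also run, which asks whether the genes of a list move on balance in 1 direction and makes no comparison with other genes. Members of a list were counted both by the adjusted p over all genes tested and by the p adjusted over the list alone.

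The genes named for a comparison were those with the 5 largest rises and the 5 largest falls among called genes with a mean of at least 2 CPM, no overlap between the libraries of the groups and a symbol that is not of a predicted gene, clone or pseudogene. Up to 3 members with the smallest adjusted p were added for each of the 6 lists with the smallest camera p. Il1b, Il6, Tnf, Ccl2, Ccr2, Cd68, Emr1 and Arg1 were named in every comparison. Emr1 is the older symbol of Adgre1 and Irg1 that of Acod1. Other members of lists serve as examples beside their list's count. Where a gene outside this rule is singled out, the text says that it was chosen after its values were seen.

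The sample titles and the authors' tables disagree on 2 graft libraries. The library titled cold-ischemia replicate 2 stands among the shock libraries in the tables, and the library titled shock replicate 3 stands among the cold-ischemia libraries. The groups of the titles were kept for every main result. Results under the grouping of the tables, without the 2 libraries in dispute, and with the 6 grafts as 1 group were added after the data were examined.

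The alternative settings were DESeq2-type size factors, upper-quartile scaling, the Wald test of DESeq2 1.42.0, no filter on low counts, a fit of only the 6 libraries compared, the replicate number as a block, a minimum of 2-fold and each library left out in turn. Both comparisons with naive lungs share their controls, so their overlap was set beside 20 simulated data sets of unchanged groups. A correction for GC content and gene length was fitted for the 6 grafts against naive lungs. Other splits of the libraries into groups of the same sizes were refitted, 10 for 3 against 3 libraries and 84 for 6 against 3.

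The test was checked on simulated counts drawn from the means and library sizes of the real libraries, with 15637 genes tested. A different set of 200 genes was changed in each graft group, and a further list of 20 genes in cold-ischemia grafts. All of these differed between the simulated graft groups, where only the set changed in shock grafts was counted as recovered. For cold-ischemia grafts against naive lungs it recovered 3 of 67 genes changed by 1.5-fold, 26 of 67 changed by 2-fold and 59 of 66 changed by 4-fold, with 4 false calls. For shock grafts against naive lungs it recovered 4 of 67, 28 of 67 and 60 of 66 at these sizes, with 5 false calls. For shock grafts against cold-ischemia grafts the numbers were 8 of 67, 33 of 67 and 62 of 66, with 8 false calls. Camera called the changed list of 20 genes in the simulated cold-ischemia comparison, with adjusted p = 2.3e-41, and 0 of 46 unchanged lists. Genes were simulated independently and the lists held random genes, so this does not check camera on lists whose genes vary together.

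Genes that share reads with near-identical copies are uncertain, because the counting could assign such reads to either copy. Among the genes named these are the pairs Hspa1a and Hspa1b, Saa1 and Saa2, Hba-a1 and Hba-a2, and the pseudogene H2-Ea-ps. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9. The authors' FPKM values, and gene fusions, which STAR-Fusion reports, were left out of the comparisons. The values of a further gene are not reported here.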

Results

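The series asks what low blood volume in a lung donor does to the transplanted lung, with macrophages entering the lung and early graft injury as its subjects. RNA was measured in whole left lungs of mice. Naive lungs came from C57BL/6 mice without surgery. Cold-ischemia grafts were C57BL/6 left lungs kept at 0 °C for 24 h, transplanted into Balb/C mice and reperfused for 2 h. Shock grafts went through the same storage and reperfusion after the donor had spent 4 h in hypovolemic shock, a loss of circulating volume that held mean arterial pressure at 15 ± 5 mmHg, and 20 h of recovery. Each group had 3 libraries. Changes of named genes are given as log2 fold changes. Total counts were 29572273, 18913487 and 34986276 in naive replicates 1, 2 and 3, 24269799, 25848362 and 22447575 in the cold-ischemia replicates, and 26555560, 21925550 and 23677327 in the shock replicates. Transcripts of mitochondrial genes took 1.76% to 2.58% of the counts of a library. The airway secretory gene Scgb1a1 was the most abundant gene in all 9 libraries, at up to 2.90% of the counts.

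The group of 2 graft libraries is in doubt. The titles place 1 of them in the cold-ischemia group (replicate 2) and the other in the shock group (replicate 3), while the authors' deposited tables place each in the opposite group. Fold changes between the graft groups computed from the grouping of the tables correlated with the log2 fold changes in the authors' deposited table across 11673 genes with r = 0.981 and had the same sign at 99.9% of genes. With the grouping of the titles these values were 0.639 and 73.8%. Genes are not independent replicates. Groups below are those of the titles unless the grouping of the tables is named. A further limit applies to every comparison with naive lungs, because the labels of all 3 naive libraries and of 0 of the 6 grafts cite a record of another series, so batch and group cannot be told apart.

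The first principal component, with 64.3% of the variance, parted the naive lungs from all 6 grafts. Naive libraries lay between -95.1 and -85.1 on it and grafts between 23.5 and 70.0. The second, with 11.5%, set shock replicate 2 apart from the other grafts, at 62.3 against -29.6 to 11.1. The closest pair of grafts was cold-ischemia replicate 1 and shock replicate 3, with a correlation across genes of 0.994, and the next was cold-ischemia replicate 2 and shock replicate 1, with 0.991.

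**Figure D1:**
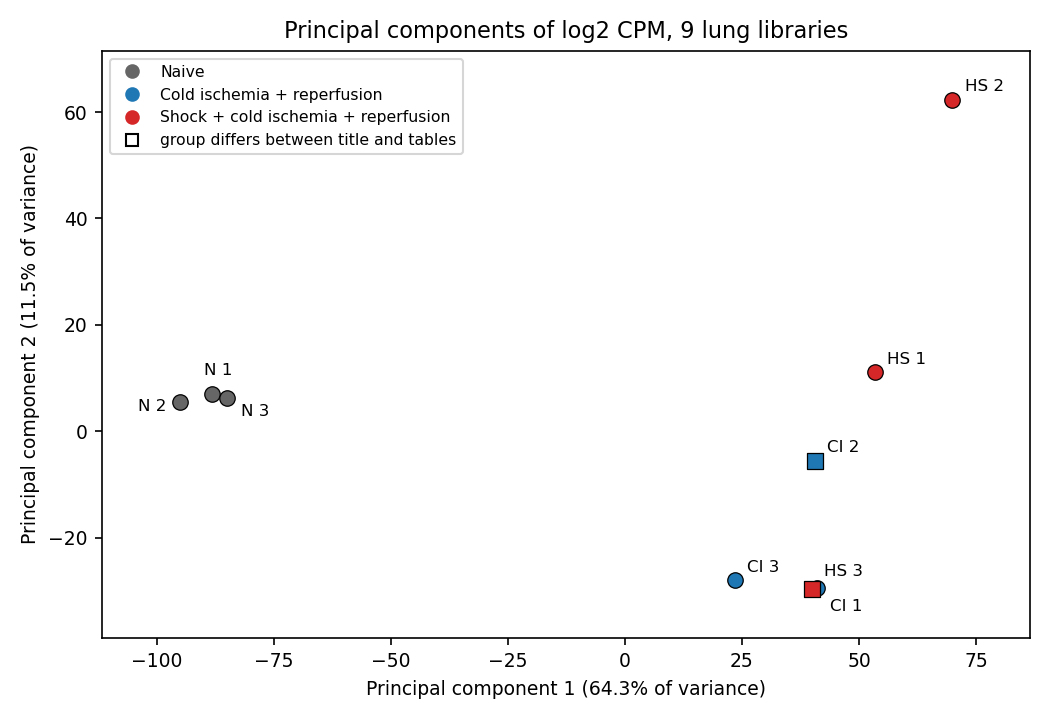
Principal components 1 (64.3% of the variance) and 2 (11.5%) of log2 CPM, with 1 point per library coloured by the group of its title, and squares for the 2 libraries whose group differs between titles and tables. Naive lungs (N) lie left of all grafts, and shock replicate 2 (HS 2) lies apart from the other grafts at 62.3 on the vertical axis.

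Cold-ischemia grafts were compared with naive lungs to see what storage, transplantation and 2 h of reperfusion had changed. Inflammatory mediators rose from near absence in naive lungs to high levels in the grafts. Cxcl2 and Cxcl1, chemokines that attract neutrophils, reached 451 ± 171 and 572 ± 165 CPM from 0.0730 ± 0.0716 and 0.311 ± 0.0220 CPM in naive lungs. Il6, a cytokine of the acute inflammatory response, reached 216 ± 148 CPM from 0.0539 ± 0.0469 CPM. Markers of neutrophils, targets of NF-κB and most immediate early genes rose with them, while most mesothelial and B cell markers fell. Of 15834 genes tested with edgeR's quasi-likelihood test, 4846 passed an adjusted p of 0.05, with 2768 higher and 2078 lower in the grafts.

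The largest rises were those of Cxcl2 (log2 fold change 12.34 ± 0.53, adjusted p = 7.4e-07), Il6 (11.66 ± 0.69, adjusted p = 1.7e-06), Cxcl1 (10.82 ± 0.33, adjusted p = 7.4e-08) and Irg1 (10.54 ± 0.59, adjusted p = 1.3e-06), whose enzyme makes itaconate in activated macrophages. Cxcl1 and Cxcl2 are protein-coding genes on chromosome 5, at 90891241 to 90893115 and 90903899 to 90905909 of mm10. Il10, an anti-inflammatory cytokine, had no read in any naive library and 5.16 ± 1.44 CPM in the grafts, at least 38.0-fold higher (adjusted p = 1.4e-05). The largest falls were those of Ankrd63 (-5.91 ± 0.50, adjusted p = 1.4e-05), Bnc1, a transcription factor of mesothelium (-5.24 ± 0.54, adjusted p = 5.9e-05), Chst4, a carbohydrate sulfotransferase (-4.60 ± 0.73, adjusted p = 0.00091), Pck1, an enzyme of gluconeogenesis (-4.44 ± 1.06, adjusted p = 0.00914), and Upk3b, a uroplakin of mesothelium (-4.35 ± 0.88, adjusted p = 0.00386). Without naive replicate 2 Pck1 was at -3.72 and without cold-ischemia replicate 3 at -5.38, and without naive replicate 1 Irg1 was at 11.89. Over the alternatives Cxcl2 ran from 11.97 to 13.04 and Il6 from 10.95 to 11.98. In naive replicates 1, 2 and 3 Cxcl2 had 5, 0 and 3 reads and Il6 had 3, 0 and 3. The size of these rises is therefore uncertain. By the rule for named genes, the 3 grafts lay on 1 side of the 3 naive lungs at each of these genes. At Pck1 the margin was small, with 0.572 CPM in naive replicate 1 and 0.508 CPM in cold-ischemia replicate 3. Naive replicates 2 and 3 held 10.1 and 6.20 CPM of Pck1.

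Of 22 cytokines and chemokines, 20 rose and 0 fell (20 adjusted over the list alone), with a median log2 fold change of 6.96, or 6.59 with Il10 at its lower bound. Csf3, which drives neutrophil production, rose by 9.97, Ccl7, a monocyte attractant, by 8.43, and Il1a, an alarm cytokine, by 5.73. Csf3 had 3, 1 and 1 reads in naive replicates 1, 2 and 3, so the size of its rise is uncertain. Il33 (0.28) and Ccl12 (1.05) did not pass. All 17 genes of NF-κB feedback and endothelial adhesion rose (17 adjusted over the list alone), with a median of 3.42. They included Nfkbie, an inhibitor of NF-κB (3.05 ± 0.13), Tnfaip3, which restrains NF-κB signalling (6.02 ± 0.27), and Sele and Icam1, which hold leukocytes on endothelium (7.40 and 3.22). All 18 neutrophil markers rose as well (18 adjusted over the list alone), with a median of 4.71, among them Ly6g (5.87), S100a8 (4.74) and the neutrophil collagenase Mmp8 (5.37). Of 14 genes of macrophages under inflammatory stimulation 12 rose (12 adjusted over the list alone). This list shares Il1b, Tnf, Il6 and Ccl3 with the cytokines. Its costimulatory genes Cd80 and Cd86 rose by 3.26 and 2.44, and Nos2, the inducible nitric oxide synthase, was at -0.30 without passing. Camera ranked each of these lists above other genes, with adjusted p = 1.1e-55 for cytokines, 2.8e-51 for NF-κB feedback, 2.5e-31 for neutrophil markers and 1.9e-23 for the macrophage list. With an estimated correlation the adjusted p-values were 0.0104, 0.00843, 0.0418 and 0.0156.

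Of 18 immediate early genes, 16 rose and 1 fell (17 and 1 adjusted over the list alone). Fosb and Atf3, transcription factors induced within minutes of stress, rose by 6.94 and 5.63, while Klf4, a factor also expressed in endothelium, fell by 0.88. The camera adjusted p was 4.4e-21, against adjusted p = 0.0586 with an estimated correlation. Of 14 genes of coagulation and fibrinolysis, 9 rose and 1 fell (10 and 1 adjusted over the list alone). Plaur, the receptor of urokinase, rose by 4.06, and F3, tissue factor, by 2.90. Thbd, a receptor through which thrombin loses its clotting activity, fell by 0.76. Camera gave adjusted p = 1.9e-10, and adjusted p = 0.0411 with an estimated correlation, so this list and the 4 before the immediate early genes kept their calls with an estimated correlation and no other list of this comparison did.

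Of 13 genes of the NRF2 response to oxidants, 10 rose (10 adjusted over the list alone), led by Slc7a11, a cystine carrier (6.77), with Srxn1 (3.94) and the heme-degrading enzyme Hmox1 (2.38). Its camera adjusted p was 3.3e-08, against adjusted p = 0.242 with an estimated correlation. Of 4 genes of metal binding and zinc transport, 3 rose (3 adjusted over the list alone), including the metallothioneins Mt1 (4.70) and Mt2 (5.81). The camera test gave adjusted p = 7.4e-07, and adjusted p = 0.0586 with an estimated correlation. Of 14 genes of the unfolded protein response, 10 rose (12 adjusted over the list alone), among them the chaperone Hspa5 (2.73), with camera adjusted p = 1.3e-06 and adjusted p = 0.172 with an estimated correlation. Of 15 heat shock genes, 6 rose (8 adjusted over the list alone), with Hspa1a at 4.60 and Hspb1 at 2.26, camera adjusted p = 0.00558 and adjusted p = 0.625 with an estimated correlation. Of 16 genes induced by hypoxia, 7 rose and 1 fell (8 and 1 adjusted over the list alone). Adm, which encodes a vasodilator peptide, rose by 3.90 and the hexokinase gene Hk2 by 3.21, with camera adjusted p = 0.0012 and adjusted p = 0.139 with an estimated correlation. Of 14 targets of p53, 8 rose and 2 fell (8 and 2 adjusted over the list alone), with Cdkn1a, a cell cycle inhibitor, at 3.36 and Bbc3, a promoter of apoptosis, at -0.83. By camera the adjusted p was 6.5e-05, and adjusted p = 0.152 with an estimated correlation.

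Of 22 genes induced by type I interferon, 15 rose (17 adjusted over the list alone). Cxcl10, a chemokine for T cells, rose by 8.72 and Rsad2, an antiviral enzyme, by 5.30. Its camera adjusted p was 3.4e-07, against adjusted p = 0.393 with an estimated correlation. In the same grafts all 18 neutrophil markers were higher, as given above. Of 13 genes of pyroptosis and necroptosis, 5 rose (7 adjusted over the list alone), including the inflammasome sensor Nlrp3 (4.96) and the inflammatory caspase Casp4 (2.90), with camera adjusted p = 0.00014 and adjusted p = 0.222 with an estimated correlation. Of 16 acute phase genes, 8 rose (9 adjusted over the list alone), with the serum amyloid gene Saa3 at 3.76 and Lcn2, which binds bacterial iron carriers, at 2.54. The list had camera adjusted p = 0.00173, and adjusted p = 0.264 with an estimated correlation.

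Of 20 markers of monocytes and macrophages, 6 rose and 2 fell (7 and 2 adjusted over the list alone), with Cd14, a receptor for bacterial lipopolysaccharide, at 4.52 and the chemokine receptor Cx3cr1 at -1.78. The camera adjusted p was 0.0179, against adjusted p = 0.625 with an estimated correlation. Of 18 genes of resolving or alternatively activated macrophages, 6 rose (6 adjusted over the list alone), with the cytokine signalling inhibitor Socs3 at 5.33 and Il4ra, a receptor chain for interleukin-4, at 2.37. Camera gave adjusted p = 0.0024, and adjusted p = 0.0657 with an estimated correlation. Of 8 mesothelial markers, 5 fell and 1 rose (7 and 1 adjusted over the list alone), with Lrrn4 at -4.32 and Wt1, a mesothelial transcription factor, at -2.57, while Krt19, a keratin found in other epithelia too, was at 1.74. The camera test gave adjusted p = 0.00461, and adjusted p = 0.23 with an estimated correlation. Of 11 B cell markers, 8 fell (10 adjusted over the list alone), with Ms4a1, the B cell antigen CD20, at -1.89, camera adjusted p = 8.9e-05 and adjusted p = 0.264 with an estimated correlation. Of 18 endothelial markers, 5 fell and 1 rose (5 and 1 adjusted over the list alone), with the apelin receptor Aplnr at -3.95 and Sox17 at -2.57. By camera the adjusted p was 0.0184, and adjusted p = 0.691 with an estimated correlation.

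Among the 8 genes followed in every comparison, Il1b rose from 4.31 ± 2.76 to 384 ± 81.2 CPM (log2 fold change 6.47 ± 0.45, adjusted p = 4.3e-06), Tnf by 7.21 ± 0.40, Il6 as given above, and Ccl2, which attracts monocytes, from 0.580 ± 0.242 to 191 ± 40.8 CPM (8.31 ± 0.44). Ccr2, the receptor of Ccl2 on monocytes, fell from 27.8 ± 6.60 to 12.0 ± 2.56 CPM (-1.22 ± 0.26, adjusted p = 0.00484). The macrophage genes Cd68 (0.47 ± 0.23, adjusted p = 0.158), Emr1 (0.71 ± 0.33, adjusted p = 0.127) and Arg1 (-0.31 ± 0.40, adjusted p = 0.599) did not pass. Cd68 passed without shock replicate 3 (adjusted p = 0.0429) and in a fit of only the 6 libraries (0.0189), within a range of up to 0.369 over the alternatives. Emr1 passed without cold-ischemia replicate 3 (adjusted p = 0.0433), within a range of up to 0.557.

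Of the 46 lists tested in cold-ischemia grafts, 22 were called. Those with no call included the markers of alveolar macrophages, where 2 of 16 rose and 1 fell (camera adjusted p = 0.778), of alveolar type 2 cells, where 1 of 14 fell (0.958), and of club and ciliated cells, where 0 passed. No list was called in a comparison in which the signs of its median, mean and camera direction differed. In cold-ischemia grafts, where none of the lists that follow was called, smooth muscle had a median of 0.04, a mean of -0.28 and the direction down, alveolar type 2 cells 0.20, 0.04 and down, replication histones 0.02, 0.12 and down, dendritic cells -0.72, 0.10 and up, and circadian genes 0.32, -0.02 and up. The median of all genes was -0.04 under TMM and -0.22 under upper-quartile scaling, under which 39.3% of the called genes were higher, against 57.1% under TMM, and 7 endothelial markers fell and 0 rose.

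**Figure D2:**
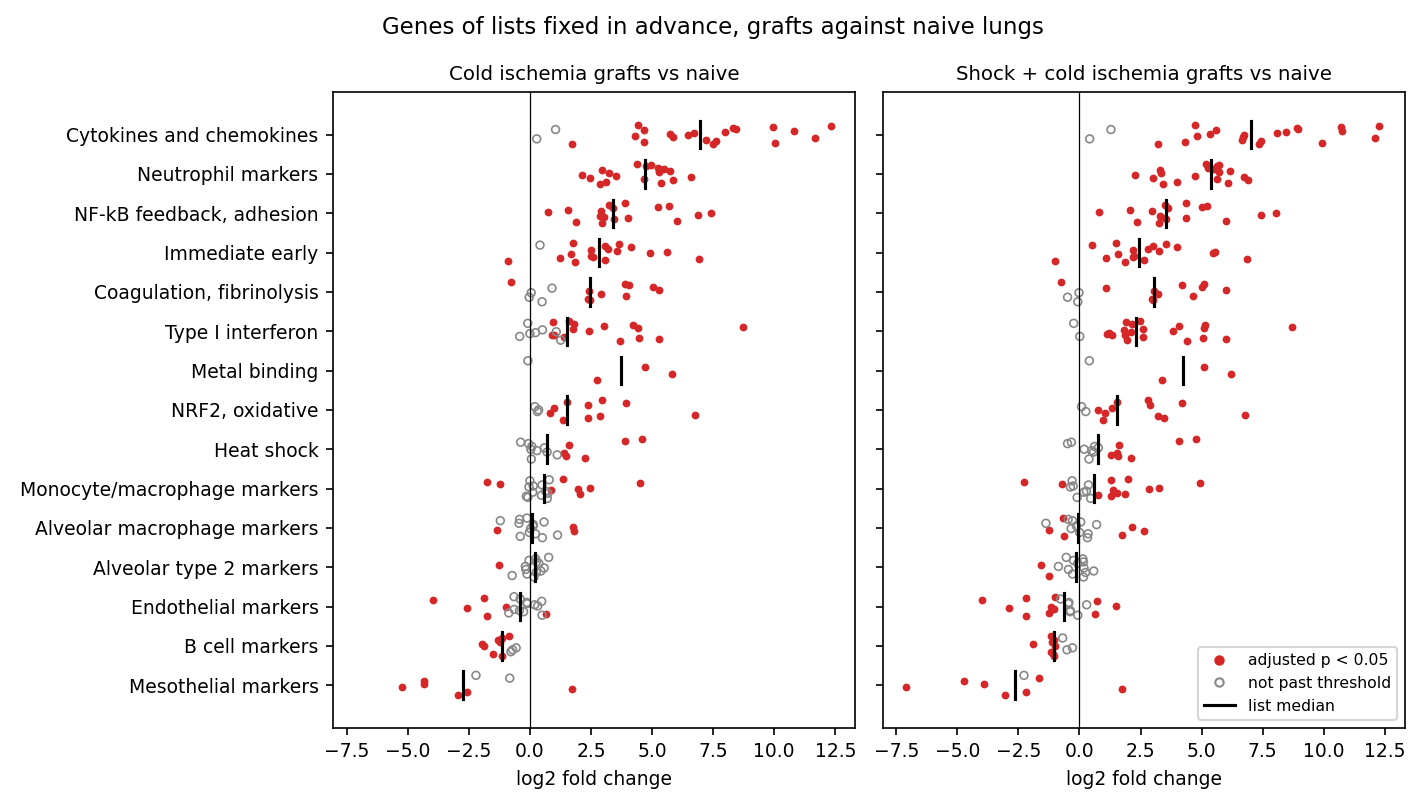
Log2 fold change against naive lungs of the members of 15 gene lists, in cold-ischemia grafts (left) and shock grafts (right), with 1 point per gene, filled where the adjusted p was under 0.05, a bar at the median, and Il10 drawn at its fitted value. All 18 neutrophil markers lie above 0 in both panels, and most mesothelial markers lie below it.

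Shock grafts were compared with naive lungs to see the state of a graft whose donor had been in shock. Cxcl2, Il6 and other mediators rose here too, with Cxcl2 at 430 ± 35.4 CPM and Il6 at 293 ± 11.7 CPM, and every neutrophil marker on the list rose. Of 22 genes induced by interferon 20 rose, while 6 of 8 mesothelial, 8 of 11 B cell and 8 of 18 endothelial markers fell. Of the 15834 genes, 6319 passed, with 3483 higher and 2836 lower. Whether a gene differed between the graft groups was tested separately and is given further on.

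Cxcl2 (12.27 ± 0.53, adjusted p = 5e-07), Il6 (12.10 ± 0.69, adjusted p = 1.2e-06), Irg1 (10.84 ± 0.60, adjusted p = 1e-06) and Cxcl1 (10.76 ± 0.33, adjusted p = 7.7e-08) rose most. Ifi202b, an interferon-inducible gene of mice, had no read in any naive library and was at least 100.1-fold higher in the grafts (adjusted p = 0.00034), with 9.79, 25.8 and 5.15 CPM in shock replicates 1, 2 and 3, so that replicate 2 held most of its mean. Bnc1 fell furthest, with 3 reads in the 3 grafts against 649 in the 3 naive lungs, a ratio of 148 (counting interval 50.4 to 720). Ankrd63 (-4.94 ± 0.46), Gas1, a membrane protein named for growth arrest (-4.83 ± 0.50, adjusted p = 5e-05), Lrrn4 (-4.73 ± 0.79) and Car3, a carbonic anhydrase of fat and muscle (-4.49 ± 0.94, adjusted p = 0.00356), followed. Without naive replicate 2, which had 97.8 CPM against 7.87 and 31.6, Car3 fell by 3.29, and without shock replicate 1 Lrrn4 fell by 6.00. Without naive replicate 1 Irg1 was at 12.18. Over the alternatives Cxcl2 ran from 11.9 to 12.97, Ankrd63 from -5.65 to -4.62 and Bnc1 from -7.29 to -5.81. The naive reads of Cxcl2 and Il6 given above were few, so the size of their rises is uncertain here too. The library titled cold-ischemia replicate 2, which the authors' tables place with the shock libraries, held 6 reads of Bnc1. By the rule for named genes, the 3 grafts lay on 1 side of the 3 naive lungs at each of these genes.

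Of the 22 cytokines and chemokines, 20 rose (20 adjusted over the list alone), with a median log2 fold change of 7.02, or 6.70 with Il10 at its bound. Csf3 was at 10.72, again against few naive reads, Ccl7 at 8.93 and Osm, a cytokine of the interleukin-6 family, at 4.75. All 17 NF-κB feedback and adhesion genes rose (17 adjusted over the list alone), with Nfkbie at 3.34 ± 0.14, Relb at 3.24 and the platelet and endothelial selectin Selp at 7.43. All 18 neutrophil markers rose (18 adjusted over the list alone), with a median of 5.39, among them Ly6g (6.90), the chemokine receptor Cxcr2 (4.72) and Retnlg (5.62). Of the 14 genes of stimulated macrophages, 11 rose (11 adjusted over the list alone), with Cd80 at 3.18. Of 14 genes of coagulation and fibrinolysis, 10 rose and 1 fell (10 and 1 adjusted over the list alone), with Plaur at 4.19 and Thbd at -0.76. Of 4 metal binding and zinc genes, 3 rose (4 adjusted over the list alone), with Mt2 at 6.19. Camera gave adjusted p = 3.4e-48, 4.8e-46, 3.3e-30, 7.3e-19, 1.1e-09 and 2.3e-07 for these lists in this order. They were the 6 lists of this comparison whose calls held with an estimated correlation, where the adjusted p-values were 0.0111, 0.0063, 0.035, 0.0174, 0.035 and 0.0493.

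The other called lists lost their calls with an estimated correlation. Of 18 immediate early genes, 17 rose and 1 fell (17 and 1 adjusted over the list alone), with Fosb at 6.86 and Klf4 at -0.99, camera adjusted p = 2.4e-15 and adjusted p = 0.109 with an estimated correlation. Of 22 genes induced by type I interferon, 20 rose (20 adjusted over the list alone), with a median of 2.32 and with Cxcl10 at 8.70, Rsad2 at 5.98 and the ubiquitin-like Isg15 at 4.08. The list had camera adjusted p = 3.4e-12, and adjusted p = 0.251 with an estimated correlation. Of 13 NRF2 genes, 11 rose (11 adjusted over the list alone), with Hmox1 at 3.46, camera adjusted p = 9.1e-08 and adjusted p = 0.277 with an estimated correlation. Of 13 pyroptosis and necroptosis genes, 10 rose (10 adjusted over the list alone), with Casp4 at 3.48 and Ninj1, which ruptures the membrane of dying cells, at 2.69. Camera gave adjusted p = 1.9e-06, and adjusted p = 0.169 with an estimated correlation. Of 16 acute phase genes, 11 rose (11 adjusted over the list alone), with Saa3 at 6.69, camera adjusted p = 0.00111 and adjusted p = 0.28 with an estimated correlation. Saa1, another serum amyloid, had 3 reads in the naive lungs and 331 in the grafts, a ratio of 161 (counting interval 54.7 to 786), and the reads could belong in part to Saa2. Of 14 unfolded protein genes, 10 rose (12 adjusted over the list alone), with camera adjusted p = 0.00025 and adjusted p = 0.28 with an estimated correlation. Among these grafts shock replicate 2 stood apart on the second principal component, as given above.

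Of 20 monocyte and macrophage markers, 10 rose and 2 fell (10 and 2 adjusted over the list alone). Cd14 was at 4.93, the integrin Itgam at 2.85 and the clotting factor F10 at 3.27, while Cx3cr1 was at -2.28. The camera test gave adjusted p = 0.00553, and adjusted p = 0.575 with an estimated correlation. Of 18 endothelial markers, 8 fell and 3 rose (8 and 3 adjusted over the list alone). Aplnr was at -3.97, Sox17 at -2.88 and Calcrl, a receptor of vasodilator peptides, at -2.20, while Nos3, the endothelial nitric oxide synthase, was at 1.48. By camera the adjusted p was 0.00545, and adjusted p = 0.575 with an estimated correlation. Of 14 fibroblast markers, 6 fell (7 adjusted over the list alone), with the collagens Col3a1 and Col1a1 at -2.85 and -1.47 and elastin, Eln, at -2.70. The list had camera adjusted p = 0.0356, and adjusted p = 0.593 with an estimated correlation. Col1a1 ran from 257 to 828 CPM in naive lungs and from 85.7 to 262 CPM in shock grafts, so the groups overlapped. Col3a1 ran from 471 to 1750 CPM and from 32.1 to 235 CPM. Shock replicate 2 was the lowest at both collagens. Of 12 smooth muscle and pericyte markers, 3 fell (3 adjusted over the list alone), with Lmod1 at -2.46 and Higd1b at -1.67, camera adjusted p = 0.0236 and adjusted p = 0.711 with an estimated correlation. Of 8 mesothelial markers, 6 fell and 1 rose (7 and 1 adjusted over the list alone), with Upk3b at -3.91, camera adjusted p = 0.00545 and adjusted p = 0.277 with an estimated correlation. Of 11 B cell markers, 8 fell (9 adjusted over the list alone), with camera adjusted p = 0.00303 and adjusted p = 0.455 with an estimated correlation.

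Of the 8 genes followed in every comparison, Il1b reached 457 ± 115 CPM (6.72, adjusted p = 3.2e-06), Tnf rose by 6.64 and Ccl2 reached 288 ± 119 CPM (8.90). Over the alternatives Il1b ran from 6.47 to 7.37. Cd68, a lysosomal protein of macrophages, rose from 30.3 ± 2.76 to 50.8 ± 18.7 CPM (0.75 ± 0.24, adjusted p = 0.0275), and Ccr2 fell from 27.8 ± 6.60 to 16.7 ± 4.31 CPM (-0.73 ± 0.25, adjusted p = 0.0406). Emr1 (0.46, adjusted p = 0.287) and Arg1 (0.68 ± 0.39, adjusted p = 0.186) did not pass. Both calls lay near the threshold. Upper-quartile scaling gave Cd68 0.52 with adjusted p = 0.0900, and a fit of only the 6 libraries gave 0.74 with adjusted p = 0.0554. Without naive replicate 1, 2 or 3 or shock replicate 1 or 2, the adjusted p of Cd68 was 0.0720, 0.0604, 0.0898, 0.0584 and 0.0933 and the log2 fold change 0.75, 0.80, 0.67, 0.75 and 0.46, and without shock replicate 3 the adjusted p was 0.0015. Without naive replicate 1 or 2, cold-ischemia replicate 1 or 2 or shock replicate 1 or 3, the adjusted p of Ccr2 was 0.125, 0.128, 0.0517, 0.0506, 0.0730 and 0.108 and the log2 fold change -0.63, -0.64, -0.73, -0.73, -0.77 and -0.54, and without both libraries in dispute Ccr2 was at -0.54 with adjusted p = 0.116. Arg1 passed without shock replicate 3 (1.02, adjusted p = 0.0261), within a range of 0.0247 to 0.453 over the alternatives.

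Of the 46 lists, 23 were called in shock grafts. Those with no call included class II antigen presentation, where 4 of 10 genes fell (4 adjusted over the list alone, camera adjusted p = 0.0523), alveolar macrophages, where 3 of 16 rose and 3 fell (0.855), and alveolar type 2 cells, where 2 of 14 fell (0.371). The median of all genes was -0.06 under TMM and -0.28 under upper-quartile scaling, under which 36.5% of the called genes were higher, against 55.1% under TMM, and 10 endothelial markers fell and 1 rose.

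**Figure D3:**
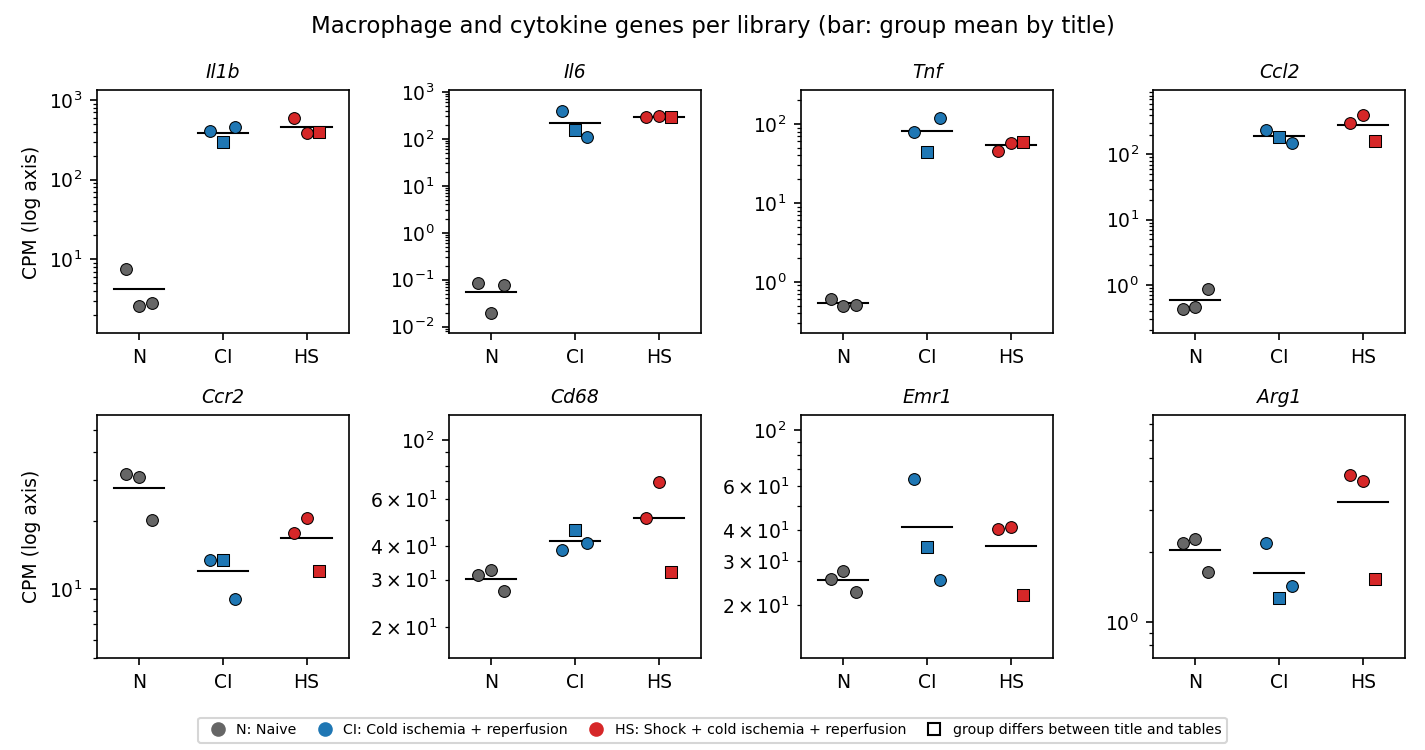
CPM on a log axis of the 8 genes followed in every comparison, with 1 point per library, a bar at the mean of the 3 libraries of a title group, and libraries without a read drawn at 0.02 CPM. Il1b, Il6, Tnf and Ccl2 are higher in all 6 grafts than in the naive lungs, and the points of the graft groups overlap at every gene.

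The changes against naive lungs in the graft groups had much in common. The called genes of both comparisons numbered 4345, all in the same direction, with 2607 higher and 1738 lower. Under upper-quartile scaling 5012 were shared, with 2053 higher and 2959 lower, so the balance of rises and falls depended on the scaling. Independent lists of these sizes would share 609 higher and 372 lower genes. In 20 simulated data sets of unchanged groups, where both comparisons shared simulated naive libraries, 0 genes were shared. With no gene changed almost none is called, so this 0 was fixed in advance and does not measure the effect of shared controls. The 3 naive libraries cannot be split into parts of 2, so part of the excess over independent lists may come from the shared controls. The log2 fold changes correlated across genes with r = 0.942 against a simulated 0.493. Their covariance was 1.28 against a simulated 0.0570, a difference of 1.22 with the covariance from shared controls taken off. By the grouping of the tables r was 0.902, with 4661 genes shared in the same direction and 2 in opposite directions. Without the 2 libraries in dispute r was 0.859, with 3586 and 4 such genes. The grouping of the titles thus gave the highest of these correlations.

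Shock grafts were compared with cold-ischemia grafts to see what shock in the donor added to the graft. By the titles, no single gene could be told apart between the groups with edgeR's test, and no list held with an estimated correlation. Oas2, an antiviral enzyme, was at 15.6 ± 5.53 CPM in shock grafts and 6.23 ± 1.45 CPM in cold-ischemia grafts, and Irf7, which drives interferon production, was at 103 ± 43.8 and 44.5 ± 14.7 CPM. The collagens Col1a1 and Col3a1 were at 190 ± 92.4 and 146 ± 104 CPM in shock grafts, against 506 ± 84.7 and 540 ± 134 CPM. None of these differences passed the test, and each had adjusted p = 0.671. In all 0 of 15834 genes were called. At an unadjusted p of 0.05 the count was 1152, where chance gives 792, but it depended on single libraries, with 533 without cold-ischemia replicate 3, 618 without shock replicate 2, 644 in a fit of only the 6 libraries and 2696 without shock replicate 3. DESeq2 called 8, with 7 higher and 1 lower.

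Camera called 20 of the 46 lists. None held with an estimated correlation, where every list named here had adjusted p = 0.641, and fry called 0. Of the 22 interferon genes 0 passed (6 higher adjusted over the list alone), with a median log2 fold change of 0.85, with Oas2 at 1.32 ± 0.31, Ifi44 at 1.13 ± 0.29 and Irf7 at 1.21 ± 0.32. Its camera adjusted p was 3.8e-15, against adjusted p = 0.641 with an estimated correlation. Of the 18 neutrophil markers 0 passed (3 higher adjusted over the list alone), with a median of 0.56 and with Cxcr2 at 1.20 ± 0.33 and Ly6g at 1.03 ± 0.30. Camera gave adjusted p = 3.2e-06, and adjusted p = 0.641 with an estimated correlation. The medians were 0.36 for pyroptosis and necroptosis (camera adjusted p = 0.00012), with Nlrc4 at 0.88 and Ripk3 at 0.87, -0.49 for smooth muscle (0.00034), with Tagln at -0.67 ± 0.33, -0.52 for fibroblasts (0.00035), with Col1a1 at -1.41 ± 0.44 and Col3a1 at -1.89 ± 0.63 (-0.46 and -0.61 by the grouping of the tables), and -0.26 for alveolar type 1 cells (0.00042), with Cldn18 at -0.55. In these 4 lists 0 genes passed, each with adjusted p = 0.641 with an estimated correlation. Shock replicate 2, which stood apart from the other grafts, had 21.2 CPM of Oas2 and 32.1 CPM of Col3a1.

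The macrophage and cytokine genes followed in every comparison did not pass between the graft groups. The log2 fold change was 0.25 ± 0.35 for Il1b (adjusted p = 0.841), 0.44 ± 0.38 for Il6 (0.743), -0.57 ± 0.29 for Tnf (0.671), 0.59 ± 0.31 for Ccl2 (0.671) and 0.48 for Ccr2 (0.671). It was 0.28 for Cd68 (0.742), -0.26 ± 0.33 for Emr1 (0.825) and 1.00 ± 0.40 for Arg1 (0.671). In the simulated data for this comparison the test found 33 of 67 genes changed by 2-fold and 8 of 67 changed by 1.5-fold, so differences of these sizes could be missed. Many genes were changed in the simulated data, which makes the adjusted p easier to pass. The share found may therefore be lower in the real comparison, where the smallest adjusted p was 0.671.

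By the grouping of the authors' tables, which was examined after the conflict was seen, genes did differ between the graft groups. Of 10 class II antigen presentation genes 4 fell and of 12 smooth muscle genes 2 fell in shock grafts, and both lists had adjusted p = 0.612 with an estimated correlation. Akr1c14, a hydroxysteroid dehydrogenase on chromosome 13 at 4049011 to 4090422, stood at 299 ± 28.5 CPM in shock grafts against 89.5 ± 10.5 CPM. Tmem252 stood at 69.5 ± 17.1 against 396 ± 68.6 CPM. With edgeR's quasi-likelihood test 124 genes passed, with 36 higher and 88 lower. An adjusted p under 0.05 was held by 483 genes in the authors' deposited table, with 176 higher and 307 lower.

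The largest rises by this grouping were those of Msln, a mesothelial surface protein (2.68 ± 0.41, adjusted p = 0.0205), Gdpd2, a glycerophosphodiesterase (2.68 ± 0.38, adjusted p = 0.0179), Ptprn2 (2.20, adjusted p = 0.0306), Pla1a, a phospholipase (1.92 ± 0.19, adjusted p = 0.00766), and Akr1c14 (1.74 ± 0.14, adjusted p = 0.00232). The largest falls were those of Dbp, a transcription factor of the circadian clock (-3.49 ± 0.65, adjusted p = 0.0413), Grp, a neuropeptide (-2.72, adjusted p = 0.0373), Aplnr (-2.60 ± 0.37, adjusted p = 0.0179), Tmem252 (-2.51 ± 0.28, adjusted p = 0.00841) and Mettl21e, a methyltransferase of muscle (-2.40, adjusted p = 0.0373). Akr1c14 and Pla1a passed with any single library left out, at adjusted p up to 0.0484 and 0.0493. Tmem252 lost its call without shock replicate 1 (0.0664), and every other gene of this paragraph lost its call without cold-ischemia replicate 1, shock replicate 1 or shock replicate 3, at adjusted p from 0.0664 to 0.146. Dbp, Grp and Mettl21e lost theirs without naive replicate 1 or cold-ischemia replicate 3 as well, and Grp and Mettl21e without naive replicate 2. Without cold-ischemia replicate 1, shock replicate 1 or shock replicate 3, Msln was at 2.31, 2.84 and 2.71. In the same fits Aplnr was at -2.49, -2.45 and -2.27 and Grp at -2.69, -3.37 and -2.72. In a fit of only the 6 libraries Msln, Gdpd2, Ptprn2, Grp, Aplnr and Mettl21e did not pass (0.0651 to 0.101).

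Of 10 class II genes, 4 fell by this grouping (8 adjusted over the list alone), with a median log2 fold change of -1.27. H2-Eb1 (-1.46 ± 0.21, adjusted p = 0.0179), H2-Aa (-1.60 ± 0.24, adjusted p = 0.0199) and H2-Ab1 (-1.41 ± 0.26, adjusted p = 0.0386) encode chains of the molecules that present antigen to helper T cells. The camera test gave adjusted p = 1.8e-14, and adjusted p = 0.612 with an estimated correlation. Of 12 smooth muscle and pericyte genes, 2 fell (4 adjusted over the list alone), which were Higd1b (-1.06) and Tagln, an actin-binding protein (-1.08, adjusted p = 0.0451), with camera adjusted p = 5.2e-06 and adjusted p = 0.612 with an estimated correlation. Of 12 dendritic cell genes, 1 fell (4 adjusted over the list alone), the chemokine Ccl22 (-1.34 ± 0.24, adjusted p = 0.0373), with camera adjusted p = 0.00174 and adjusted p = 0.612 with an estimated correlation. Of 18 endothelial genes, 2 fell (2 adjusted over the list alone), Aplnr and Gpihbp1, a carrier of lipoprotein lipase (-1.13, adjusted p = 0.0179), with camera adjusted p = 0.00238 and adjusted p = 0.612 with an estimated correlation. Of 20 monocyte and macrophage genes, 1 rose (6 adjusted over the list alone), the hemoglobin scavenger receptor Cd163, from 7.63 ± 1.43 to 16.2 ± 3.51 CPM (1.08 ± 0.20, adjusted p = 0.0406). By camera the adjusted p was 0.00079, and adjusted p = 0.612 with an estimated correlation. In the same grouping 12 cardiac muscle genes had a median of -1.82, with 0 passing (1 lower adjusted over the list alone), camera adjusted p = 0.00125 and adjusted p = 0.612 with an estimated correlation.

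These genes of class II, smooth muscle, dendritic, endothelial and macrophage lists lost their calls without single libraries. Without shock replicate 1, shock replicate 3 and cold-ischemia replicate 1 the adjusted p was 0.0673, 0.0760 and 0.0899 for H2-Aa, 0.0664, 0.0685 and 0.0694 for H2-Eb1, 0.0832, 0.143 and 0.0916 for Cd163, 0.149, 0.143 and 0.160 for Tagln, and from 0.105 to 0.146 for H2-Ab1, Higd1b and Ccl22. Gpihbp1 lost its call without either of the shock replicates (0.0664 and 0.0717). Without any 1 of the naive replicates H2-Ab1, Higd1b, Cd163 and Tagln lost theirs as well, and Ccl22 without naive replicate 2 or 3, at adjusted p from 0.0535 to 0.0901. Higd1b, Ccl22, Cd163 and Tagln did so without cold-ischemia replicate 3 (0.0635 to 0.0938), Tagln with DESeq2-type size factors (0.0529), and all 8 in a fit of only the 6 libraries (0.0651 to 0.145). With replicates named by their titles, the count of 124 genes became 52 and 45 without naive replicates 1 and 2, 11 without cold-ischemia replicate 1, 504 without the library titled cold-ischemia replicate 2, and 8, 555 and 7 without shock replicates 1, 2 and 3. Without both libraries in dispute, 39 genes passed among 16068, with 9 higher and 30 lower, and 27 of them were also called by the grouping of the tables, in the same direction. The remaining libraries hold the same groups in both fits, so shared calls and directions are partly built in and give no separate support. Among the 39, chosen here after their values were seen, were Akr1c14 (1.73), Pla1a (1.74), Tmem252 (-2.67), Ccl22 (-1.69) and Tagln (-1.44). Of the 8 genes followed in every comparison 0 passed by the grouping of the tables with edgeR's test. Tnf had the smallest adjusted p, at -0.82 with adjusted p = 0.102, and Cd68 followed at 0.57 with adjusted p = 0.126. DESeq2 called both, Tnf at -0.79 with adjusted p = 0.0363 and Cd68 at 0.59 with adjusted p = 0.0347.

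**Figure D4:**
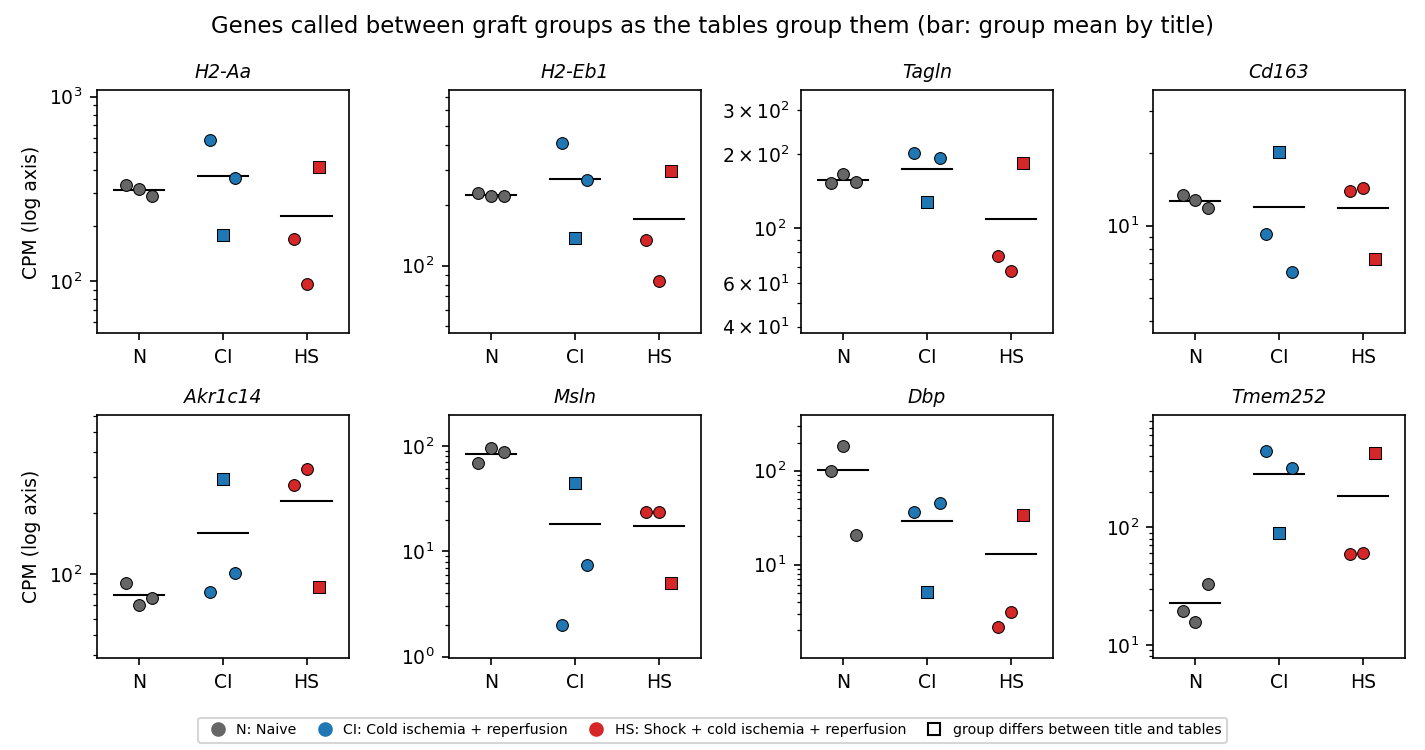
CPM per library of 8 genes that differed between the graft groups by the grouping of the tables, coloured by the group of the title, with bars at the mean of each title group and squares for the 2 libraries in dispute. At Akr1c14 and Tmem252 the square titled shock lies with the cold-ischemia libraries, and the square titled cold ischemia lies with the shock libraries. The genes were chosen because they differed by the grouping of the tables. The place of the squares was largely fixed by that choice and does not test the titles.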

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

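The grouping of the authors' tables, the fits without the 2 libraries in dispute, the joint comparison of the 6 grafts and the GC and length correction were chosen after the data were seen. Size factors, upper-quartile scaling, DESeq2, no filter and a fit of 6 libraries left the counts against naive lungs between 4697 and 5781 genes in cold-ischemia grafts and between 5844 and 7342 in shock grafts. Leaving out single libraries gave 3371 to 5662 and 4613 to 6635. The tables' grouping gave 5513 and 7307, and without the 2 libraries the counts were 4237 and 6766. A minimum of 2-fold, stricter by construction, left 2559, 3378, 2244 shared by both, and 3053 of 6453 for the 6 grafts together. Between the graft groups the titles gave 0 genes under each scaling, without a filter and with any library left out, while DESeq2 called 8, the tables' grouping 124 and the fit without the 2 libraries 39. Under the tables' grouping DESeq2 called 1073 genes, no filter 313, a fit of 6 libraries 17, and leaving out single libraries 7 to 555. That fit of 6 libraries has fewer degrees of freedom and takes its spread from the grafts alone, without the naive lungs. Why its count was lower was not tested. In cold-ischemia grafts against naive lungs by the titles, such a fit raised the count from 4846 to 5781. An estimated correlation left 5 and 6 lists called against naive lungs, in cold-ischemia and shock grafts, and 0 between graft groups. Fry, which makes no comparison with other genes, called 24, 25 and 0. Values that reversed were all short of the threshold. Between graft groups they were Il6 and Emr1 under the tables' grouping (-0.063 and 0.056), and with single libraries left out Cd68 ran from -0.015 to 0.52 and Emr1 from -0.52 to 0.21. Under the tables' grouping Il1b was -0.0036 with upper-quartile scaling, and with single libraries left out Il1b ran from -0.28 to 0.23, Il6 from -0.43 to 0.33 and Emr1 from -0.21 to 0.71. The cause was not tested. Of named genes with 1 library left out, 277 results kept direction and call in cold-ischemia grafts and 2 gained a call, and in shock grafts 267 kept both, 11 lost a call and 1 gained one. With the replicate block the counts were 4296, 5801 and 0 genes and 22, 25 and 21 lists. The same-numbered grafts did not deviate together (r = -0.39, 0.10 and 0.04), so the numbers were not taken to pair them. Depth limits statements on genes under 0.136 CPM in naive lungs and 0.149 CPM in shock grafts, where replicate 2 of each holds fewer than 3 reads.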

Other observations

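The tests of the tables' grouping against other splits, of the position of the disputed libraries along the axis of the other grafts, of the naive batch and all tests on H2-Ea-ps were chosen after the result was seen.

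Further lists against naive lungs showed the following. Of 14 genes that respond to glucocorticoids, 7 rose and 1 fell in cold-ischemia grafts (10 and 2 adjusted over the list alone), with Cebpd, a transcription factor also induced in inflammation, at 3.21 and Pdk4, which slows glucose oxidation, at 2.96. Camera gave adjusted p = 1.7e-05, and adjusted p = 0.122 with an estimated correlation. In shock grafts 8 rose and 1 fell (8 and 1 adjusted over the list alone), with Cebpd at 3.28 and Tsc22d3, a common marker of glucocorticoid action, at -0.99 (camera adjusted p = 0.00027, and adjusted p = 0.17 with an estimated correlation). Of 17 genes of extracellular matrix, 6 rose in cold-ischemia grafts (6 adjusted over the list alone), with Timp1, an inhibitor of matrix proteases, at 3.27, camera adjusted p = 0.0387 and adjusted p = 0.625 with an estimated correlation. In shock grafts 6 rose and 3 fell (6 and 4 adjusted over the list alone; 5 and 5 under upper-quartile scaling), with Timp1 at 4.63 and no call (camera adjusted p = 0.396).

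Of 10 erythroid genes, 7 rose in shock grafts (7 higher and 1 lower adjusted over the list alone), with the hemoglobin gene Hba-a2 at 2.96 ± 0.50 and Alas2, an enzyme of heme synthesis in red cells, at 2.96 ± 0.59, while camera made no call (adjusted p = 0.0779). In cold-ischemia grafts 4 rose (4 adjusted over the list alone), with Hba-a2 at 1.54 ± 0.49 and camera adjusted p = 0.248, and 3 rose and 1 fell under upper-quartile scaling. Of 12 water and ion transport genes, 6 rose in cold-ischemia grafts and 6 in shock grafts (6 and 6 adjusted over the list alone), with 3 in cold-ischemia grafts under upper-quartile scaling. They included the water channel Aqp3, at 2.29 and 2.86, and the sodium channel subunit Scnn1a, at 0.63 and 0.82, and camera made no call (adjusted p = 0.0755 and 0.0702). Of 4 genes induced by cold, 1 rose in cold-ischemia grafts and 2 in shock grafts (1 and 2 adjusted over the list alone, and 1 and 1 under upper-quartile scaling), and camera made no call (adjusted p = 0.248 and 0.236). Rbm3, an RNA-binding protein, was the one that rose in both, by 1.36 ± 0.19 and 1.60 ± 0.19.

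Between the graft groups the titles gave 0 genes and the grouping of the tables gave 124. The 3 against 3 splits of the 6 grafts number 10, too few for a share under 0.05. Every split gives at least the titles' count of 0, so that the 10 of 10 splits with as many decide nothing, and the highest other was 124, the split of the tables. That split was the 1 of 10 with 124 genes, and the highest other split gave 42. If the titles of both libraries were exchanged, each should lie nearer the other group. On the axis from the mean of cold-ischemia replicates 1 and 3 (0) to that of shock replicates 1 and 2 (1), cold-ischemia replicate 2 lay at 0.445 and shock replicate 3 at 0.170, and at the 39 genes called from the other 4 grafts the former was nearer the shock mean at 25 and the latter nearer the cold-ischemia mean at 39. The median positions at those genes were 0.590 for cold-ischemia replicate 2 and 0.115 for shock replicate 3. Shock replicate 2, which stood apart from the other grafts, helps set the shock end of the axis. Its own deviation can lengthen the axis and pull positions toward 0, so a position midway does not show a mixed state. The values lie nearer the cold-ischemia grafts for shock replicate 3 and do not decide for cold-ischemia replicate 2. Exchanged titles, a single wrong title and variation between grafts may each be the source and remain open.

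All comparisons with naive lungs could reflect the operation and reperfusion or a difference in batch. For the 6 grafts together the real split was the 1 of 84 with 6453 genes, and the highest other gave 48. This argues against chance without excluding it. Every other split puts naive lungs and grafts in the same group, which widens the spread within groups and lowers the counts. For cold-ischemia and shock grafts alone, 10 splits are too few for a share under 0.05, with 4846 and 6319 genes in the real split (1 of 10 each) and 0 in the highest other. A bias of GC content or gene length is argued against as the whole cause, since 93.4% of the calls were made in the same direction after the correction, which moved fold changes by a median of 0.0769. The naive batch cannot be told apart from the group, because 3 of 3 naive libraries and 0 of 6 grafts cite a record of another series, and the effect of the transplantation stays open with it.

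H2-Ea-ps, a class II gene on chromosome 17 at 34342933 to 34344643 whose allele in C57BL/6 mice is not transcribed, had 269 to 588 reads in each of the 6 grafts and 0 in the naive lungs. Reads shared with other class II genes are argued against, because the lowest graft ratio to H2-Aa, H2-Ab1 and H2-Eb1 predicts 665 reads in the 3 naive libraries, where 0 were seen. Induction along with class II genes is argued against, since H2-Aa, H2-Ab1, H2-Eb1 and Cd74 had a median log2 fold change of -0.043 between the 6 grafts and naive lungs. RNA of Balb/C recipient cells in the graft is a candidate explanation, and Ifi202b, the other gene on the list of recipient-strain genes with reads, was present in all 6 grafts (20 to 518 reads) and in 0 naive lungs. The share of recipient cells was not estimated. An induction private to Ifi202b stays open. For H2-Ea-ps, induction in donor cells would need transcription of the C57BL/6 allele, which is described above as not transcribed.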
